A study of Homo sapiens with 4 samples.

How the data were processed

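Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in HCT116 cells, an established human colorectal carcinoma line. Per the labels' protocols, the cells had been transduced with lentivirus carrying either the empty pSin vector or pSin with the full coding sequence of FOXD2, a forkhead transcription factor, and stable cells had been selected with puromycin. The labels name 2 control and 2 FOXD2 libraries, numbered 1 and 2 in each group. Nothing in the labels says that the libraries of a group came from separate cultures, so the spread between them may be technical. The labels give no batch or date.

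The deposited files are lists of peak intervals, with 1 list per library and no pooled list. Per the submitters' processing notes, cutadapt 3.4, Bowtie2 2.3.4.1, Picard, MACS2 2.2.7.1 and bedtools were used with the hg38 build. The notes give no role, order or setting for these tools. Peak-caller settings are not given in the sources used here, and neither is whether read ends were shifted for the Tn5 insertion. Each interval carries the authors' fold enrichment over local background at its summit, a ratio within that library. It also carries the deposited −log10 p and −log10 q of the summit, and a whole-number score that the authors' peak caller derived from −log10 q. The lowest −log10 q of the 4 lists ranged from 2.005 to 2.026. The authors' fold, −log10 p, −log10 q and score are values of single peaks within a list. They served here to describe, rank or filter peaks within that list, except that the score was not used. The fold and −log10 p also served to recover the background described below. Within-list percentiles of −log10 q also formed the strata of peak strength. No read counts per region were used, so presence or absence of a called interval was the readout.

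The comparisons used chromosomes 1 to 22 and X. Intervals on other contigs, between 0.208% and 0.251% of each list, were left out of them. Read depth is unknown. In MACS2 the fold and the Poisson p of a peak together fix its pileup and its local background. The values recovered this way matched the deposited −log10 p within 0.002 for 100% of the peaks with a value below 60. The resulting genome-wide background was 1.68 and 1.71 tags for control replicates 1 and 2, and 1.84 for both FOXD2 libraries. It scales with depth only where fragment length and genome size were set alike, which is not given in the sources used here. The lowest summit pileup of a called peak was 8 tags, and 9 in FOXD2 replicate 2, so weaker sites could not appear in a list.

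Intervals of the 4 lists that overlapped by at least 1 bp were merged into regions, and a region was in a library where that library had an interval in it. A region was gained where both FOXD2 libraries and neither control had it, and lost in the reverse case. The same counts were made for the other 2 ways to split the 4 libraries into pairs, replicates 1 against replicates 2 and the crossed split. With 3 splits no exact test of the condition can give a p below 0.333. All p-values over regions therefore compare these 4 libraries and not the condition, since regions are not replicates, and all intervals cover counting error only. The numbers of regions on the 2 sides of a split depend on how much each library detected. The geometric mean of the 2 numbers is alike in all splits under certain conditions. Libraries must detect a region independently of each other, and their differences in detection must act alike on all regions. Its interval was taken from Poisson errors.

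Gene positions came from a RefSeq table of GRCh38.p14, the same build as hg38, with 19839 protein-coding genes on these chromosomes. The table has no strand and no exons. The planned window of 1000 bp around the 5′ end was therefore replaced by 1000 bp to either side of both ends of the gene, called gene ends here. Each region was assigned to the nearest protein-coding gene body within 100 kb in place of the nearest 5′ end. Exon, intron and UTR positions are not given for the same reason. No genome sequence was used, and the planned test of 26 sequence motifs, the forkhead motif first, was not run.

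Shares carry 95% Clopper-Pearson intervals. Gained and lost regions were compared by place and by chromosome with two-sided Fisher's exact tests, with 0.5 added to each cell for the odds ratio and its Wald interval, and Benjamini-Hochberg adjustment over the 23 chromosomes. For 17 gene lists, the odds ratio of gained to lost regions near list members against all other genes was compared with 100000 random lists matched in 5 bins of regions per gene, a two-sided permutation test. A list passed where its p, adjusted over the 17 lists, was under 0.05 and its log odds ratio lay further from 0 than in both other splits. The 476 listed entries gave 474 list members, since 2 entries were older symbols of genes in the same list. The splits, the place, chromosome and list tests, the lists and the rule for named genes were fixed before the data were examined. A test per gene was added afterwards. It asked, with a one-sided exact hypergeometric test in each direction, whether a gene had more gained or more lost regions than its number of regions would give, with Benjamini-Hochberg adjustment over both directions of 17552 genes, and also over the members of each list alone.

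The genes named follow a fixed rule. They are FOXD2 and FOXD2-AS1, and the 10 gained and 10 lost regions with the best rank, where the rank of a region is the worse of its 2 within-list percentiles by −log10 q. They are also the 10 genes gaining and the 10 losing a gene-end peak by that rank, the 5 genes with most gained minus lost regions and the 5 with most lost minus gained regions, and up to 4 members per list with most gained plus lost regions. Genes outside the rule are marked where they appear, and some items that the rule names are not reported here.

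The procedures were tested on simulated data over the 122856 regions and 17552 genes. Planted gained and lost regions were recovered at 100%, which their separate simulated intervals fixed in advance. With 200 planted each way and the other regions drawn independently in each library, 6750 regions were called gained. Recovery therefore does not show what share of gained and lost calls is due to the groups. In that simulation the ratio of geometric means of the group split to the higher other split was 1.03. The list test gave an unadjusted p under 0.05 for 3.5% of unchanged lists of 30 genes, and for 20%, 55% and 69% of lists with a planted odds ratio of 2, 3 and 5. The test per gene recovered 64% of genes of 15 or more regions in which 35% of the regions were planted as gained, and called 0 genes when regions were drawn at random. That draw treated regions as independent, so it does not cover neighbouring regions that change together.

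Alternatives tried were peaks of −log10 q 5 or more only, lists shortened to equal length by −log10 p, windows of 100 bp to each side of the summits in place of intervals, and sharing only where 50% of the shorter interval was covered. Others were −log10 q of 5 or more in both libraries that have a region, leaving out each library, a gene-end window of 2000 bp, a distance of 20 kb, Fisher's exact test for the lists, a replicate block, and the nearest gene end in place of the gene body. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1, and plots used matplotlib 3.10.9.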

Results

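Accessible chromatin was mapped in HCT116 colorectal carcinoma cells carrying either the empty vector (control, 2 libraries) or the vector with FOXD2 (2 libraries). The question was which open regions differ when FOXD2, a forkhead transcription factor, is supplied to these cells. The lists held 77752 intervals in control replicate 1, 72796 in control replicate 2, 82739 in FOXD2 replicate 1 and 64675 in FOXD2 replicate 2. They covered 38.5, 34.9, 39.5 and 31.3 Mb in that order. The median of the authors' fold enrichment was 5.67 and 5.78 in the controls and 5.30 and 5.52 in the FOXD2 libraries. The intervals merged into 122856 regions, of which 39933 (32.5%) were in all 4 libraries and 50109 (40.8%) in only 1 library. A peak at a gene end was present in all 4 libraries for 13208 (66.6%) of 19839 protein-coding genes.

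The gene supplied by the vector was examined first. FOXD2 (chromosome 1, 47438044 to 47440691, hg38) had a strong peak across its lower-coordinate end in all 4 libraries, at 47437242 to 47438237 in control replicate 1 and at 47437376 to 47438525 in FOXD2 replicate 1. Inside the gene body both FOXD2 libraries had a further interval, 676 bp at 47438790 to 47439465 in replicate 1 and 689 bp at 47438805 to 47439493 in replicate 2. Their −log10 q was 17.1 and 17.7, at the 67.4 and 68.4 percentiles of their lists. Control replicate 1 had a shorter interval there, 320 bp at 47439012 to 47439331 with a −log10 q of 8.29 (percentile 37.7), and control replicate 2 had none. An interval just outside the lower-coordinate end of FOXD2, at 47436539 to 47436746 in control replicate 1 and 47436513 to 47436995 in control replicate 2, was in neither FOXD2 library. No interval overlapped the long non-coding RNA gene FOXD2-AS1 (47432133 to 47434641). The vector carries the FOXD2 coding sequence, so reads from integrated vector can map inside the gene, and the interval there cannot be assigned to the genomic copy.

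**Figure D1:**
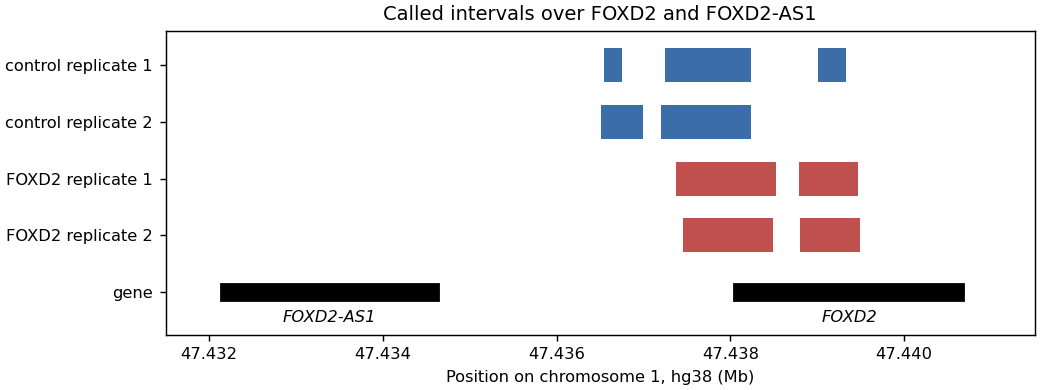
Called intervals of each library (bars, to scale) over FOXD2 and FOXD2-AS1 on chromosome 1, with hg38 position in Mb on the horizontal axis. Both FOXD2 libraries have an interval of 676 and 689 bp inside FOXD2, where control replicate 1 has 320 bp and control replicate 2 has none.

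Across the genome, 4777 regions were gained with FOXD2 and 4758 were lost. The highest-ranked gained regions all lay inside genes, led by MCCC1, a subunit of methylcrotonyl-CoA carboxylase (chromosome 3, 183073844 to 183074516, −log10 q 36.1 and 30.7 in FOXD2 replicates 1 and 2). They were followed by TTC3, GOLGA1, the striatin gene STRN, RGS22, the glycosyltransferase gene MGAT5, VPS13D, KCTD1, the transporter gene ABCC5 and NAV2, all at or above the 78.7 percentile of both FOXD2 lists. The highest-ranked lost region lay inside the protocadherin gene PCDH7 (chromosome 4, 30802557 to 30802961, −log10 q 33.2 and 31.8 in control replicates 1 and 2). Other high-ranked lost regions were one inside STAT3, a cytokine-activated transcription factor (chromosome 17, 42324958 to 42325410, −log10 q 29.0 and 29.6), and regions inside CEP162, VMP1, SHOC1, CAPZB and TLK1 and 22947 bp from USP12.

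Most gained and lost regions were weaker than these. The median −log10 q of gained regions was 7.81 and 7.38 in FOXD2 replicates 1 and 2, and that of lost regions was 7.22 and 7.03 in control replicates 1 and 2. Regions in all 4 libraries had medians of 25.9 and 24.7 in control replicates 1 and 2, and of 22.8 and 17.7 in FOXD2 replicates 1 and 2. Shared regions were thus weaker in both FOXD2 libraries than in both controls. Median widths were 386 bp for gained, 351 bp for lost and 748 bp for shared regions. Leaving out 1 library relaxes the definition of both sets, and gained regions then numbered between 6986 (without control replicate 2) and 22597 (without FOXD2 replicate 2) and lost regions between 6868 (without FOXD2 replicate 2) and 19198 (without control replicate 2).

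The groups were separated by more regions than the other splits of the libraries. Splitting replicates 1 from replicates 2 gave 4246 regions only in the pair numbered 1 and 1200 only in the pair numbered 2. The crossed split gave 1738 regions only in control replicate 1 and FOXD2 replicate 2, and 2967 only in control replicate 2 and FOXD2 replicate 1. The geometric mean of the 2 counts was 4767.5 (95% interval 4672.8 to 4864.2) for the groups, against 2257.3 (2186.1 to 2330.7) and 2270.8 (2204.6 to 2339.1) for the others. The Jaccard index of covered bases was 0.570 between the controls, 0.528 between the FOXD2 libraries and 0.512 to 0.526 between libraries of different groups. The mean within groups exceeded that between groups by 0.0279, where the 4 values between groups had an SD of 0.00614. The same difference was −0.00894 and −0.0190 in the other splits. The excess came mostly from the controls, since the FOXD2 pair (0.528) lay little above the highest value between groups (0.526). Overlap by number of intervals, which also depends on list length, went both ways. FOXD2 replicate 2 overlapped 61.5% of the intervals of FOXD2 replicate 1, and the controls 66.1% and 63.5%. For the intervals of FOXD2 replicate 2 the shares were 79.5% with FOXD2 replicate 1, and 74.6% and 72.4% with the controls. With 3 splits the smallest exact p is 0.333, so no exact test over the splits could pass 0.05.

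**Figure D2:**
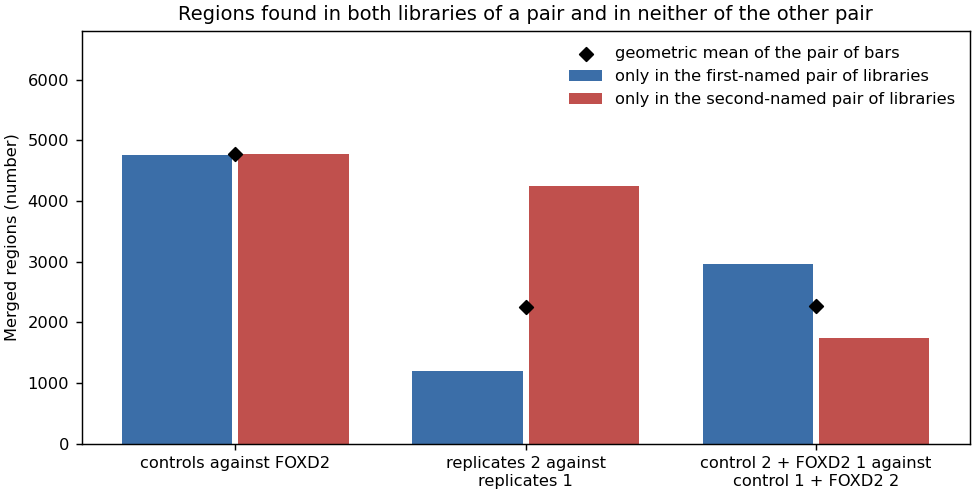
Number of merged regions found in both libraries of a pair and in neither of the other pair, for the 3 ways to split the 4 libraries, with the geometric mean of each pair of bars as a diamond. The group split has 4758 and 4777 regions, with a geometric mean above those of the other splits (2257.3 and 2270.8).

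Gained regions lay at gene ends less often than lost regions. Of 4777 gained regions, 179 lay within 1000 bp of an end of a protein-coding gene (3.75%, 95% interval 3.23 to 4.33), against 388 of 4758 lost regions (8.16%, 7.39 to 8.97). The odds ratio was 0.439 (0.366 to 0.527, two-sided Fisher's exact p = 4.006e-20), and 0.771 (Fisher's exact p = 5.156e-06) without control replicate 1. In the other splits it was 1.11 (0.875 to 1.41, Fisher's exact p = 0.409) and 1.27 (1.02 to 1.56, Fisher's exact p = 0.0325). Gained regions lay inside genes away from gene ends more often than lost regions, 53.7% against 48.5% (odds ratio 1.23, 1.14 to 1.34, Fisher's exact p = 3.364e-07). The shares outside genes were 42.5% and 43.4% (odds ratio 0.967, 0.892 to 1.05, Fisher's exact p = 0.420). Among regions in all 4 libraries 31.6% lay at gene ends, and among those in 1 library 6.16%. Of all intervals in a list, 20.7% and 21.8% lay at gene ends in the controls, and 19.1% and 22.9% in FOXD2 replicates 1 and 2, so the shares of whole lists did not separate the groups. In lists shortened to equal length, an alternative chosen after seeing the data, they were 23.4% in both controls and 22.3% and 22.9% in the FOXD2 libraries.

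At the level of genes, 92 of 19839 had a gene-end peak in both FOXD2 libraries and neither control, and 167 had the reverse. The replicate split gave 179 genes for the pair numbered 1 and 37 for the pair numbered 2, and the crossed split gave 71 and 80. Genes gaining a gene-end peak included TM4SF4, a tetraspan membrane protein gene (chromosome 3, 149473546 to 149474023, −log10 q 21.0 and 22.9), the serine protease genes TMPRSS11F and TMPRSS13, and COL17A1, a hemidesmosomal collagen gene. The others by rank were GNB4, CAPN8, CEP70, ACCSL, GPR183 and the cytokine gene TNFSF15. Genes losing a gene-end peak were led by PTGIR, the prostacyclin receptor gene (chromosome 19, 46625217 to 46625559, −log10 q 12.9 and 17.0 in the controls), followed by RGS1, the natural killer cell receptor gene KLRC2, DIRAS2 and the class II histocompatibility gene HLA-DOA. PDCL2, IL1RAPL1, LRRC14B, NPB and PRAC2 completed this group. The controls had different regions at the ends of IL1RAPL1. The counts of 92 and 167 genes fell to 52 and 98 where both libraries with the region needed a −log10 q of 5 or more. Without control replicate 1 they were 228 and 334, without control replicate 2 158 and 478, and without FOXD2 replicate 1 203 and 519. Without FOXD2 replicate 2 the direction turned, with 350 genes gaining and 283 losing a gene-end peak, where gained regions over the genome also outnumbered lost ones (22597 against 6868).

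**Figure D3:**
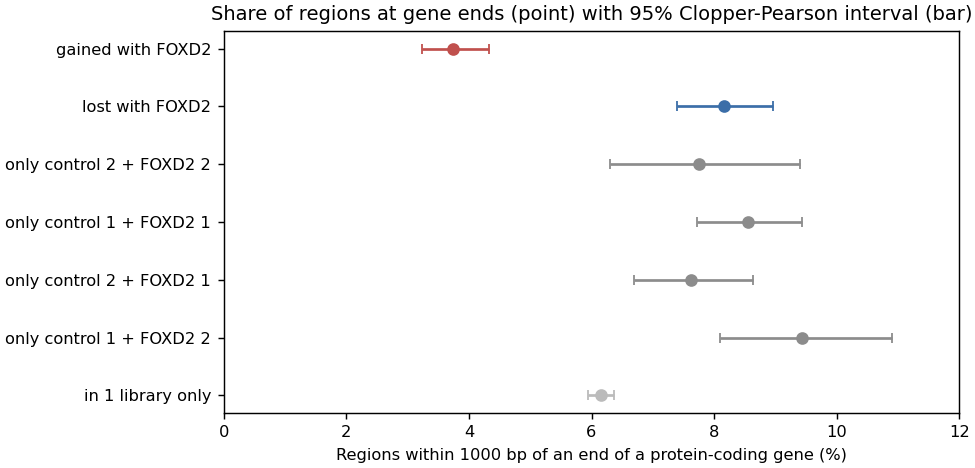
Percentage of regions within 1000 bp of an end of a protein-coding gene (points) with 95% Clopper-Pearson intervals (bars), for regions found in only the named pair of libraries or in 1 library. Gained regions stand at 3.75%, below lost regions at 8.16% and below the 4 sets from the other splits.

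Lost regions were concentrated at PCDH7, which encodes a cell-adhesion protocadherin, and gained regions around JUN, which encodes an AP-1 transcription factor subunit. Of the 50 regions assigned to PCDH7 (chromosome 4, 30720369 to 31146800), 15 were lost and 0 gained, spread from 30745021 to 31060544 inside the gene. PCDH7 had a peak in 39 and 38 of these regions in control replicates 1 and 2, against 14 and 11 in FOXD2 replicates 1 and 2. Of the 18 regions assigned to JUN (chromosome 1, 58780791 to 58784047), 7 were gained and 0 lost, from 58745753 to 58875176. A peak was present in 10 and 8 of the 18 in the controls and in 18 and 15 in the FOXD2 libraries. The gained region at 58782328 to 58782905 lay inside the gene. The others lay outside it and were assigned to JUN as the nearest gene. A peak across the higher-coordinate end of JUN was in all 4 libraries. It stood at percentiles 94.0 and 87.4 in control replicates 1 and 2, and 88.4 and 74.8 in FOXD2 replicates 1 and 2. In the exact hypergeometric test per gene, chosen after seeing the data, PCDH7 (adjusted p = 1.011e-05) and JUN (adjusted p = 0.0494) passed among 17552 genes. By the same exact test 310 genes had an unadjusted p under 0.05 for gained and 300 for lost regions. In both other splits 0 genes passed, with 254 and 270 genes at an unadjusted p under 0.05 in the replicate split and 235 and 317 in the crossed split. Those splits held fewer differing regions (5446 and 4705, against 9535), so the test had less power in them.

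The remaining genes with most regions on balance did not pass this test. AOPEP had 7 gained and 0 lost regions (exact test, adjusted p = 0.750), and the calpastatin gene CAST had 6 gained, the ubiquitin ligase gene HECW1 had 5 and the mitochondrial ribosomal protein gene MRPS28 had 5, each with 0 lost. On the other side IQSEC1 had 7 lost regions, and DCBLD2, the retinoid X receptor gene RXRA and the WNT effector gene TCF7L2 had 6 lost each, with 0 gained. Without any 1 of the 4 libraries JUN still had 6 to 8 gained regions on balance, but its call was lost (exact test, adjusted p from 0.201 to 1), as gained regions over all genes then numbered from 6986 to 22597. The call was also lost with lists of equal length (6 on balance, exact test, adjusted p = 0.295), summit windows (6, adjusted p = 1), a distance of 20 kb (3, adjusted p = 1) or the nearest gene end (7, adjusted p = 0.0861). PCDH7 lost its call only with the nearest gene end (5 lost regions on balance, exact test, adjusted p = 1), and regions were also lost in the 2 Mb to each side of it (6 of 35, with 0 gained). In the 2 Mb to each side of JUN, 10 of 102 regions were gained and 2 lost.

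**Figure D4:**
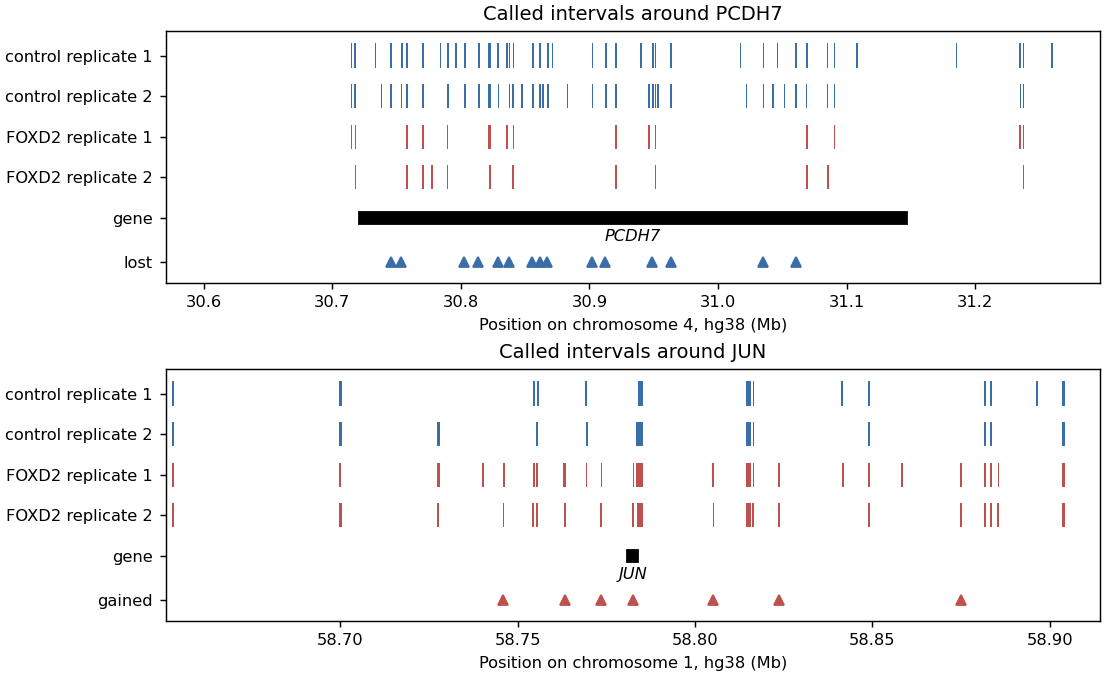
Called intervals of each library around PCDH7 (chromosome 4) and JUN (chromosome 1), with hg38 position in Mb on the horizontal axis, the gene as a black bar and triangles at lost (PCDH7, 15) and gained (JUN, 7) regions. Intervals narrower than a visible line are widened for display, and the FOXD2 libraries have fewer intervals at PCDH7 and more around JUN than the controls.

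No gene list passed as a whole. By the permutation test, 0 of the 17 lists had an adjusted p under 0.05, the smallest being 0.594, and 0 had an unadjusted p under 0.05, as also by Fisher's exact test over regions. The smallest permutation p belonged to the HOX genes, which pattern the body axis, with 1 gained and 6 lost regions at 33 genes (odds ratio 0.225, 0.0381 to 1.33, permutation p = 0.0698). HOXA3, HOXA13, HOXB8 and HOXB9 each had 1 lost region. Genes of AP-1, the immediate early response and NF-kB had 13 gained and 6 lost regions (odds ratio 2.03, 0.797 to 5.19), with JUN holding 7 of the gained and DUSP5 3 of the lost ones.

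Adjusted over the list alone, 2 list members passed the exact test per gene, JUN (adjusted p = 0.000169) and E2F7, a cell cycle repressor gene with 4 gained and 0 lost of 8 regions (adjusted p = 0.0108). Over all genes tested only JUN did, and E2F7 had an adjusted p of 0.750 by that exact test.

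Lists on the identity of colon cells were split in both directions. Epithelial junction and identity genes had 14 gained and 11 lost regions (odds ratio 1.23), with 4 gained and 1 lost at EHF, 2 and 1 at GRHL2 and 1 and 2 at ST14. CDH1, the E-cadherin gene, had 1 of each. Mesenchymal genes had 5 gained and 11 lost regions (0.467, 0.169 to 1.29), among them 1 and 2 at COL5A1, 0 and 1 at FN1, 1 and 0 at ITGA5 and 1 of each at AXL. Intestinal differentiation genes had 4 gained and 9 lost regions (0.462, 0.150 to 1.42), with 2 lost each at HNF4G and NEUROD1. WNT target and intestinal stem cell genes had 13 gained and 11 lost (1.15), with 2 gained and 1 lost at RNF43, 1 and 2 at LEF1 and 2 lost at CCND1.

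Forkhead genes had 14 gained and 10 lost regions (1.35, 0.610 to 2.99), of which FOXO1 held 3 gained and 1 lost. Cell cycle genes had 13 and 7 (1.76, 0.721 to 4.30), with 3 and 1 at CDK6. Interferon response genes had 6 and 3 (1.82), with 2 gained at OASL. Targets of p53 had 6 and 4 (1.41), with 1 gained each at BBC3 and FAS, 1 lost at BTG2 and 1 of each at FDXR. Genes of histone H3K4 methylation and enhancer cofactors had 7 and 3 (2.10, 0.589 to 7.46), with 2 gained at KDM6A, an H3K27 demethylase gene. Genes of TGF-beta and BMP signalling had 13 of each (0.977), with 3 gained and 1 lost at LTBP1 and 3 lost at LTBP2.

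Markers of other cell types gave 1 gained and 2 lost regions for fibroblasts, 0 and 2 for leukocytes, 6 and 6 for endothelium and 6 and 10 for neural cells, where RBFOX3 held 3 and 5. Ubiquitous control genes had 5 gained and 3 lost regions, 3 gained at YWHAZ and 2 lost at HPRT1. In simulated lists of 30 genes, odds ratios of 2, 3 and 5 reached an unadjusted p under 0.05 in 20%, 55% and 69% of lists.

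**Figure D5:**
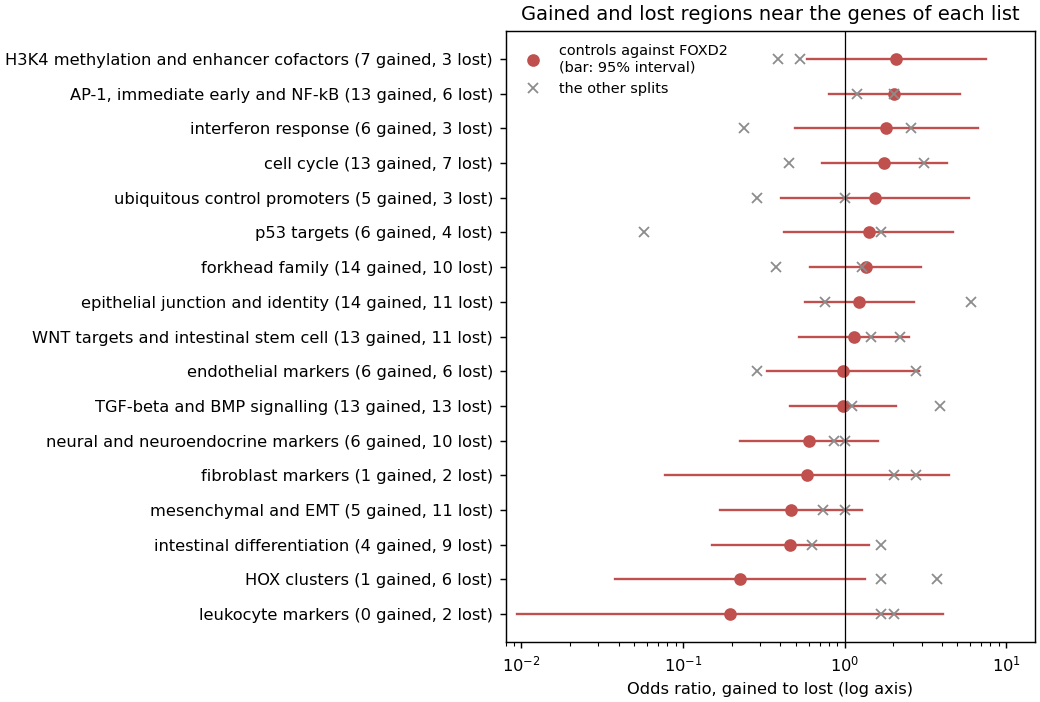
Odds ratio of gained to lost regions near the genes of each list against all other genes (log axis), with 95% Wald intervals for the group split (red) and the values of the other splits as crosses. The interval of each of the 17 lists includes 1.

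Chromosomes 7 and 19 had fewer gained than lost regions relative to the rest of the genome. Chromosome 19 held 115 gained and 199 lost regions (odds ratio 0.566, 0.449 to 0.715, Fisher's exact test, adjusted p = 2.89e-05) and chromosome 7 held 224 and 304 (0.721, 0.604 to 0.861, adjusted p = 0.00326). By Fisher's exact test chromosome 22 passed in the same direction (74 and 108, adjusted p = 0.0499), and chromosomes 6 (319 and 253, adjusted p = 0.0440) and 15 (167 and 122, adjusted p = 0.0489) passed in the other. Without regions at gene ends, by Fisher's exact test, chromosomes 7 (adjusted p = 0.00849) and 19 (adjusted p = 0.00830) kept an adjusted p under 0.05. The other 3 did not (Fisher's exact test, adjusted p from 0.0829 to 0.0956), but their odds ratios moved little, from 1.27 to 1.26 on chromosome 6, from 1.38 to 1.32 on chromosome 15 and from 0.679 to 0.680 on chromosome 22. In the other splits 0 chromosomes passed Fisher's exact test after adjustment, with 1 and 2 at an unadjusted p under 0.05. Those splits held fewer differing regions, so passing was harder in them. In the crossed split the odds ratios of chromosomes 7, 22, 19, 6 and 15 were 0.762, 1.46, 1.22, 0.838 and 1.26. On a log scale those of chromosomes 7 and 22 were nearly as large as in the group split, so such sizes also arose without the group contrast. The count of 5 passing chromosomes fell to 1 with peaks of −log10 q 5 or more, with summit windows, or with such peaks required in both libraries, and to 0 without control replicate 1.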

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

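Of the tests below, the ratio of geometric means, the tests on gene density, the shares in lists of equal length and the test per gene were chosen only after the results they bear on were seen. The odds ratio without FOXD2 replicate 2 had been chosen before the data were examined, but its use as a test of an explanation, and both p-values given for JUN against its flanks, came after the results were seen.

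Intervals on contigs outside the numbered chromosomes and X entered no comparison, and on 3 of the 15 such contigs with at least 10 intervals in all both FOXD2 libraries had more than both controls. GL000225v1, a contig assigned to chromosome 14 without a position, had 28 and 23 intervals with FOXD2 and 15 and 16 in the controls (mean 25.5 with FOXD2). The unplaced contig GL000216v2 had 11 and 9 against 6 and 6 (mean 10), and the unplaced GL000219v1 had 7 and 7 against 6 and 5 (mean 7). On 2 contigs both FOXD2 libraries had fewer, and chance alone puts 16.7% of contigs without ties in each direction.

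The group split gave 9535 gained and lost regions, and the highest total of the other splits was 5446, but 3 splits are too few for a share under 0.05. Unequal detection between libraries that acts alike on all regions would leave the geometric means alike. The ratio of the group split to the higher other split was 2.10. Copy-number blocks would set neighbouring regions of different genes in the same direction, which held for 53.8% of pairs (95% interval 52.5 to 55.0), below the 60% set beforehand. Leaving out the 10 windows of 10 Mb with unequal gains and losses left the ratio at 2.10, so neither explanation accounts for the excess as a whole. Regions in all 4 libraries were weaker in both FOXD2 libraries than in both controls (median −log10 q 22.8 and 17.7 against 25.9 and 24.7). The ratio does not cover such a difference where it acts unevenly over regions. An effect of FOXD2 may underlie the excess, but any other difference between the cell populations carrying the 2 vectors, or between the preparations of the groups, would look alike and was not tested.

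Gained regions lay at gene ends less often than lost regions (odds ratio 0.439, and 0.771 without control replicate 1). The odds ratio was 0.494 (0.446 to 0.547) without FOXD2 replicate 2, the library with the fewest intervals. This cannot decide on weak detection there, since gained regions then needed only 1 library and lost regions both controls. Regions in 1 library lay at gene ends in 6.16%, against 7.62% to 9.44% for the sets of the other splits. By library the share was 7.42% and 6.61% in control replicates 1 and 2, and 5.01% and 5.86% in FOXD2 replicates 1 and 2. The odds ratio was 0.452 (0.376 to 0.544) within 25 strata of peak strength and width. It was 0.484 (0.402 to 0.583) within quintiles of gene density within 1 Mb. The values within strata and quintiles speak against strength, width or gene density as the whole cause. Away from gene ends gained regions were fewer in the most gene-dense quintile (odds ratio 0.723, 0.641 to 0.815, against 0.934 and 1.39 in the other splits), but from the sparsest to the densest quintile the ratio of gained to lost regions was 1.02, 1.26, 1.11, 1.03 and 0.796, with no steady fall. Gene ends held 20.7% and 21.8% of the intervals in the controls and 19.1% and 22.9% in the FOXD2 libraries, which does not separate the groups, and 23.4% in both controls against 22.3% and 22.9% in lists of equal length. Fewer calls in GC-rich, gene-dense sequence of the FOXD2 libraries therefore cannot be told apart from an effect of FOXD2 away from promoters, which was not tested, because these values point both ways and no genome sequence was used.

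PCDH7 lost 15 of 50 regions and JUN gained 7 of 18. Loss of a chromosome segment around PCDH7 could explain the first, since 17.1% of the 35 regions in the 2 Mb to each side were lost too (6.56 to 33.7, against 30%, 17.9 to 44.6, in the gene), and with these few regions it cannot be told apart from a change of the gene alone. For JUN, 9.80% of 102 regions in the 2 Mb to each side were gained (4.80 to 17.3), against 38.9% (17.3 to 64.3) of the 18 regions assigned to JUN. The gap only barely meets the bound set beforehand, with an upper limit of 17.29 in the flanks and a lower limit of 17.3 for JUN. That bound also ignored that JUN was chosen for its share among 17552 genes. While a permutation p allowing for the 10 genes of the segment is 0.0226, the exact p times all 17552 genes reaches 1. A gained segment therefore cannot be told apart either. An effect of FOXD2 on either gene stays open as an untested hypothesis, and on leaving out each library in turn JUN kept 6 to 8 gained regions on balance while its call was lost (adjusted p from 0.201 to 1).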

How the results depend on the processing

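The alternatives for the ratio of splits, the chromosomes and the test per gene, and the nearest gene end, were chosen after seeing the data. The gene-end odds ratio stayed below 1 and past its threshold in every alternative (0.378 to 0.771, the latter without control replicate 1). With the replicate block it was 0.677 (7.457e-48 by the Cochran-Mantel-Haenszel test). The block counts each gained and lost region in both pairs of libraries, so its p overstates the evidence. Same-numbered libraries did not deviate together in the presence of regions (correlation −0.00375 over regions). This does not exclude a common batch, since the labels give none. The block leaves 4777 gained and 4758 lost regions by its construction. The ratio of the group split to the higher other split ranged from 1.78 to 2.67, and within minus between group Jaccard was 0.0315 and 0.0332. The number of gene lists that passed was 0 in each alternative, with a smallest adjusted p of 0.0826 (HOX genes, 50% overlap). Leaving out 1 library relaxes the definition, so counts grow by construction. Gained regions then ranged from 6986 to 22597, lost regions from 6868 to 19198, genes gaining a gene-end peak from 158 (without control replicate 2) to 350 (without FOXD2 replicate 2) and genes losing one from 283 (without FOXD2 replicate 2) to 519 (without FOXD2 replicate 1), so that more genes gained than lost one without FOXD2 replicate 2. Requiring a −log10 q of 5 or more in both libraries left 52 and 98 such genes. The 5 passing chromosomes became 1 with peaks of −log10 q 5 or more, 3 with equal lengths, 1 with summit windows, 3 with 50% overlap, 1 with −log10 q of 5 in both libraries, and 0 to 4 without 1 library. The gene with more gained regions (JUN) became 0 genes with equal lengths, summit windows, 20 kb or the nearest gene end, and 0 to 1 without 1 library, where the 1 was EXOC4 without FOXD2 replicate 2, a gene outside the rule for named genes and chosen after its values were seen. The gene with more lost regions (PCDH7) became 0 with the nearest gene end, since regions deep inside this long gene are over 100 kb from its ends. Other causes were not tested. Of 1221 values of gained minus lost regions for single genes, 1000 kept their sign, 212 came to, left or crossed 0, and 9 lost their call (8 for JUN, 1 for PCDH7). The planned motif alternatives were not run, and unknown depth limits how far absence of a weak peak can be read.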

Other observations

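The tests below were added after the data were examined. Gained and lost regions were unevenly spread along some chromosomes. Of 279 windows of 10 Mb, 10 had an adjusted p under 0.05 by Fisher's exact test, against 0 of 219 and 0 of 221 in the other splits. The other splits held fewer differing regions (5446 and 4705, against 9535), so their windows were tested with less power. The region at 230 to 240 Mb of chromosome 1 had 42 gained and 10 lost regions (Fisher's exact test, adjusted p = 0.00240), and the first 10 Mb of chromosome 19 had 24 gained and 61 lost (adjusted p = 0.00638). Gains also led on chromosome 17 from 60 Mb (49 and 20), in the first 20 Mb of chromosome 6 (34 and 12, then 33 and 10) and on chromosome 8 from 120 Mb (40 and 16). Losses led on chromosome 11 from 60 Mb (21 and 47), chromosome 9 from 130 Mb (15 and 41), chromosome 3 from 90 Mb (0 and 10) and chromosome X from 150 Mb (1 and 12).

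A hypothesis formed from this was that regions change in neighbourhoods wider than single genes. Neighbouring differing regions assigned to different genes pointed the same way 3.77 percentage points more often than independent regions would (53.8%, 52.5 to 55.0, of 6057 pairs), while the other splits lay at −2.02 and −1.13 points. These pairs come from the same regions as the windows, with the 10 passing windows included. The share therefore restates the windows in part and is no separate test of the hypothesis. Regional differences may contribute a small part. Whether they lie in chromatin, in copy number or in fewer calls in GC-rich, gene-dense sequence of the FOXD2 libraries cannot be told apart here.

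Gene families grouped by the start of their symbol were asked whether any gained or lost regions on balance. By the permutation test 0 of 109 families passed, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.589. The lowest unadjusted p belonged to the PCDH symbols, with 1 gained and 21 lost regions over 9 genes, 15 of them at PCDH7 (permutation p = 0.00540). The others were the CEP symbols (13 gained and 3 lost), the olfactory receptor symbols starting with OR (7 and 22) and the MAP symbols (30 and 13).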
